A study of Homo sapiens with 27 samples.

How the data were processed

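Poly(A) RNA was sequenced from 27 subcutaneous xenografts of BON cells, 1 tumour per mouse, 13 from mice kept on rapamycin and 14 from mice switched to CC-223. The authors deposited 1 table of raw read counts per gene, with 26219 genes in rows and 1 column per tumour. Each gene carried an NCBI gene identifier, a symbol, a name and, except for 2661 genes, hg19 coordinates. Per the labels' protocols, libraries were made with a strand-keeping dUTP kit and read as single reads of 50 bases. Per the submitters' processing notes, the tools were bcl2fastq, CASAVA 1.8, TopHat and edgeR, and the genome build was hg19. The counting program, the annotation release, the use of strand in counting and any handling of mouse reads are not given in the sources used here. Reads of mouse host cells can align to the human genome at conserved genes, so a count can hold both species. Reads shared by near-identical copies (ribosomal protein and elongation factor pseudogenes, UGT2B17 and its paralogs, CEL and its pseudogene, the trypsinogens and amylases) and by overlapping or antisense genes cannot be assigned with certainty.

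Columns were matched to tumours by their titles, and 0 columns of per-sample values were left unmatched. Groups came from the titles and sources in the labels. The labels used here assign no tumour a response to CC-223, so responders and non-responders are not analysed here. No mouse number occurs in both arms, so tumours were not paired. The mitochondrial DNA genes listed in advance were not analysed here.

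The design, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The deposited counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 2 arms as groups, which left 15649 genes, and 2233 genes had no count in any tumour. Library sizes were scaled by TMM factors, dispersions were estimated, and the quasi-likelihood F test compared CC-223 with rapamycin with no covariate. Fold changes are CC-223 over rapamycin. Standard errors were taken from the fold change and its F statistic. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Levels are given as CPM, counts scaled by TMM-adjusted library sizes, computed here from the deposited counts, as mean ± SD over the tumours of an arm.

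Gene lists covered pathways downstream of mTOR, neuroendocrine and tumour state, and markers of host cells that a xenograft can hold. The 30 lists with at least 5 measured members were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, at the preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Beside it stand camera with an estimated correlation, fry, and the number of members past 0.05 adjusted over all genes and over the list alone. For the 6 host cell lists with enough members, the mean log2 CPM per tumour was compared between arms by a two-sided permutation test with 100000 resamples. The same kind of test compared each of the first 5 principal components of the 2000 most variable genes. It also compared the mean distance of tumours to the centre of their arm.

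The text names the 12 higher and 12 lower genes of smallest p among those past the threshold. It also names up to 4 members of smallest p per list that passed its test or held a passing member, and 10 genes chosen in advance (MTOR, RICTOR, RPTOR, EIF4EBP1, IRS1, IRS2, CHGA, SYP, TPH1 and MKI67). Some genes that this rule picks are left out of the text. Other genes are named as chosen after their values were seen.

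Depth was 9805981 to 29451126 counts per tumour. In simulated counts with the real means and library sizes, run on 15485 genes for CC-223 against rapamycin, the test recovered 31 of 50 genes changed 1.5-fold, 42 of 50 changed 2-fold, 49 of 50 changed 3-fold and 50 of 50 changed 4-fold. It made 2 false calls among 174 calls. The changed genes were drawn from those with a mean of at least 1 CPM. Counts were drawn for each gene apart, so variation between tumours that genes share was not simulated.

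Alternatives were RLE, upper quartile or no scaling factors, DESeq2 1.42.0, limma-voom with and without sample quality weights, other filters and thresholds, surrogate variables (sva 3.50.0), the fibroblast list as a covariate, and each tumour left out in turn. The calls were also recomputed without the 2 tumours whose libraries stood apart and with mouse number as a block. Those were chosen after seeing the data.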

Results

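BON cells, an established line of a human neuroendocrine tumour of the pancreas, were grown under the skin of nude mice. Tumours that had progressed on rapamycin, which inhibits mTOR complex 1, either stayed on rapamycin (13 tumours) or were switched to CC-223, an inhibitor of the mTOR kinase itself (14 tumours). Per the labels, the CC-223 tumours were taken 17 days after the switch, and no such day is given for the rapamycin tumours. Rapamycin at 10 mg/kg per day and a fast of 3 h are listed for all mice. RNA was sequenced from 1 tumour per mouse. Total counts per tumour ran from 9805981 to 26545198 in the rapamycin arm (median 18807378) and from 11026276 to 29451126 in the CC-223 arm (median 17988630). Levels are given as CPM, counts scaled to library size, as mean ± SD over 13 and 14 tumours. P-values of single genes and of permutation tests measure the spread between tumours of different mice, and camera at the preset correlation compares genes with one another. The closest 2 tumours, rapamycin mice 229 and 253, differed by a chi-square of 14.2 per gene, against 1 for sampling noise alone, so no 2 libraries were copies of one another. In 1 tumour of each arm, rapamycin mouse 235 and CC-223 mouse 236, 10.6% and 20.8% of genes with a mean of 1 to 5 CPM had no count, against at most 0.740% in any other tumour.

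The first question was which mRNAs differed after the switch from rapamycin to CC-223. With CC-223, mRNAs of the digestive enzymes CPA1 and CEL, the crypt glycoprotein OLFM4 and the clock component PER3 were lower, and the long non-coding RNA CCAT1 and mRNAs of the matrix proteoglycan ASPN and the nucleotide enzyme IMPDH2 were higher. In total 153 of 15649 genes changed, 91 higher and 62 lower (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). Of these, 5 rose and 23 fell by at least 2-fold. The largest fall among the named genes was that of CPA1, a carboxypeptidase of pancreatic juice (gene 1357, chromosome 7, 130020290 to 130027949, hg19), from 29.5 ± 55.7 to 1.07 ± 0.610 CPM. CEL, a bile salt dependent lipase of the pancreas (gene 1056, chromosome 9, 135937365 to 135947248), went from 23.1 ± 62.4 to 1.77 ± 1.07 CPM. The rapamycin mean of CPA1 rested largely on mice 203 (180 CPM) and 206 (121 CPM), and that of CEL on mouse 206 (230 CPM). With limma-voom the adjusted p was 0.232 for CPA1 and 0.302 for CEL, at the upper end of their ranges over 41 alternatives (from 1.64e-07 and 0.00118).

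The lower gene with the smallest p was OLFM4, a secreted glycoprotein of crypt stem cells (gene 10562, chromosome 13, 53602876 to 53626196). It fell from 314 ± 154 to 77.7 ± 50.8 CPM (log2 fold change -2.01, SE 0.30, adjusted p 0.00107), and all 14 CC-223 tumours lay below the rapamycin median. ANPEP, an aminopeptidase of the brush border, fell from 133 ± 71.4 to 55.4 ± 16.2 CPM (adjusted p 0.00312). KRT20, a keratin of intestinal epithelium, fell from 21.7 ± 9.77 to 8.08 ± 5.05 CPM. UGT2B17, which glucuronidates steroids, fell from 3.56 ± 2.52 to 0.699 ± 0.356 CPM, with reads that its paralogs may share. DDC, the decarboxylase that makes serotonin and dopamine, fell from 70.2 ± 22.1 to 37.3 ± 10.5 CPM (log2 fold change -0.91, SE 0.16). PER3, a component of the circadian clock, fell from 13.6 ± 4.67 to 5.49 ± 2.07 CPM (log2 fold change -1.31, SE 0.22, adjusted p 0.00312). Lower levels were also called for ABAT, which breaks down GABA (log2 fold change -1.03), PDCD4, an inhibitor of the translation helicase eIF4A (-0.64), and SLC25A20, the mitochondrial carnitine carrier (-0.50).

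Among the higher genes, CCAT1, a long non-coding RNA of colon cancers with no coordinates in the table, had the smallest p. It rose from 6.18 ± 1.36 to 11.4 ± 2.16 CPM (log2 fold change 0.89, SE 0.12, adjusted p 0.000953). ASPN, a matrix proteoglycan (gene 54829, chromosome 9, 95218489 to 95244844), rose from 1.63 ± 0.570 to 4.85 ± 2.10 CPM (log2 fold change 1.57, SE 0.24). PMP22, a membrane protein of myelin that epithelia also express, rose from 21.5 ± 5.95 to 37.9 ± 7.27 CPM. CAV1, the coat protein of caveolae, rose from 8.85 ± 2.85 to 15.8 ± 4.13 CPM. IMPDH2, the rate-limiting enzyme of guanine nucleotide synthesis, rose from 198 ± 24.2 to 282 ± 45.1 CPM (log2 fold change 0.51, SE 0.08, adjusted p 0.00206). LPAR3, a receptor for lysophosphatidic acid, rose from 1.84 ± 0.576 to 3.88 ± 1.17 CPM. PLK2, a polo-like kinase, rose from 301 ± 64.6 to 510 ± 170 CPM. RIN1, an effector of Ras, rose with a log2 fold change of 0.56. SEMA3A, a secreted guidance cue, rose by 0.51 on the log2 scale, SLC45A3, a solute carrier, by 0.53, and RPUSD4, a pseudouridine synthase, by 0.31. In each of these genes all 14 CC-223 tumours lay above the rapamycin median.

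**Figure D1:**
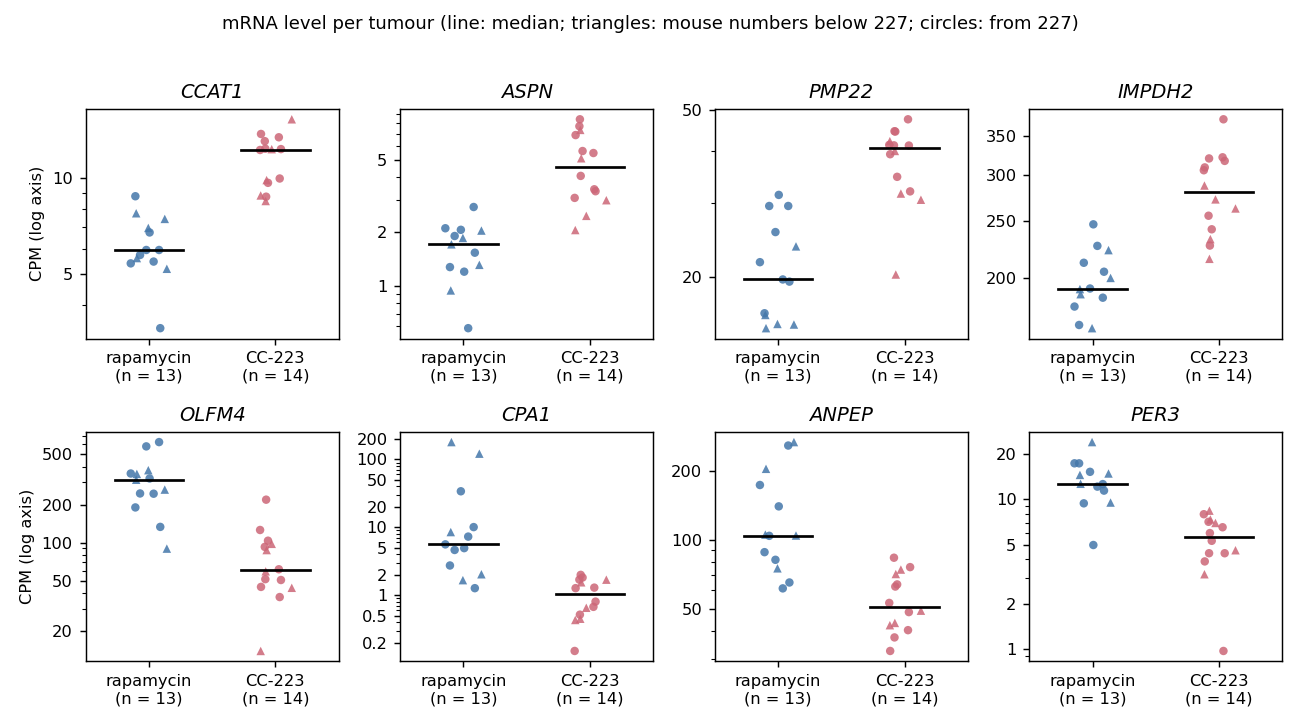
CPM on a log axis in each tumour of the 2 arms for 4 of the genes higher and 4 of the genes lower with CC-223 (points: tumours, triangles for mouse numbers below 227; line: median of the arm). For all 8 genes every CC-223 tumour lies on one side of the rapamycin median, and for CPA1 rapamycin mice 203 and 206 lie above the others.

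Leaving out 1 tumour moved the count of changed genes to between 66 (without rapamycin mouse 261) and 239 (without CC-223 mouse 245), and scaling by library totals alone gave 100 genes, 47 higher and 53 lower. Mouse numbers below 227 (5 tumours per arm) and from 227 (8 rapamycin, 9 CC-223) differed in 3780 genes; the lower part alone gave 0 changed genes (edgeR; 1728 at an unadjusted p under 0.05), and the upper part gave 15 higher and 4 lower.

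The next question was whether genes known to act together differed as groups, in 30 lists fixed in advance. At the preset correlation between genes (camera, which compares a list with all other genes) 11 lists passed, 10 higher and 1 lower with CC-223, and with an estimated correlation 0 of the 30 passed (camera; 7 at an unadjusted p under 0.05, and 7 by fry at an adjusted p under 0.05). With the fibroblast level as a covariate the interferon (adjusted p 0.0619), heat shock (0.129), angiogenic (0.0729) and endothelial (0.0815) lists missed the threshold. The clearest in its members was the list of MAPK feedback and immediate early genes, induced by signalling through ERK. Of its 26 measured members 5 rose, or 9 when adjusted over the list alone (median log2 fold change 0.21, camera adjusted p 8.95e-08, adjusted p = 0.118 with an estimated correlation). PHLDA1 rose from 342 ± 64.9 to 491 ± 117 CPM, the Eph receptors EPHA2 and EPHA4 rose by 0.48 and 0.46 on the log2 scale, and the MAP kinase phosphatase DUSP4 rose by 0.39. DUSP6, the fifth, was named after its value was seen (log2 fold change 0.44, SE 0.11, adjusted p 0.0383). With library totals alone as scaling, EPHA2, EPHA4 and DUSP4 missed the threshold (adjusted p 0.0534, 0.0778 and 0.116, the upper ends of their ranges over 41 alternatives, from 0.00129, 0.00215 and 0.000508).

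Lists of the translation machinery lay above 0 in small steps. All 74 cytosolic ribosomal protein genes had a fold change above 0 (median 0.27), but none passed the test, over all genes or adjusted over the list alone (camera adjusted p 1.01e-13, adjusted p = 0.509 with an estimated correlation). The value was 0.35 (SE 0.12) for RPS3A, 0.27 (SE 0.10) for RPL3, 0.35 (SE 0.13) for RPL14 and 0.36 (SE 0.14) for RPS9, each with copies elsewhere in the genome. Of 19 translation factors with 5-prime TOP mRNAs, whose translation depends on mTOR, 0 passed over all genes and 9 when adjusted over the list alone, all higher (median 0.22, adjusted p = 0.171 with an estimated correlation). Among them were EEF1A1 (0.27, SE 0.08), EIF4B (0.24, SE 0.07), EIF3E (0.29, SE 0.09) and EEF2 (0.19, SE 0.07). Of 33 ribosome biogenesis and MYC target genes 2 rose, or 10 when adjusted over the list alone (median 0.18, adjusted p = 0.171 with an estimated correlation). These were the nucleolar GTPase GNL3 (0.31, SE 0.06) and TSR1, which acts in maturation of the small ribosomal subunit (0.34, SE 0.08), while WDR43 (0.26) and MRTO4 (0.26) did not pass. TSR1 missed the threshold in 16 of the 27 fits without 1 tumour. Of 30 DNA replication genes 1 rose, and 1 when adjusted over the list alone: CDT1, which licenses replication origins (0.43, SE 0.09, adjusted p 0.0188). The list median was 0.19 (adjusted p = 0.431 with an estimated correlation), with 0.29 for MCM2, 0.26 for MCM4 and 0.25 for MCM3.

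Of 21 endoplasmic reticulum stress genes 3 rose, or 5 when adjusted over the list alone (median 0.13, adjusted p = 0.171 with an estimated correlation). They were the chaperones DNAJB9 (log2 fold change 0.47, SE 0.10) and HSP90B1 (0.31, SE 0.07) and the phosphatase subunit PPP1R15A (0.46, SE 0.11). PDIA6 did not pass (0.25, adjusted p 0.0510), and PPP1R15A missed the threshold without the 2 sparse libraries (adjusted p 0.0635, range over 41 alternatives 0.00091 to 0.0764). None of 14 heat shock genes passed, over all genes or adjusted over the list alone (median 0.13, adjusted p = 0.567 with an estimated correlation; HSPD1 0.26, DNAJB1 0.32, HSP90AB1 0.14, HSF1 0.09). Of 15 angiogenic factors 1 rose, and 1 when adjusted over the list alone: CXCL8, a chemokine, from 26.5 ± 13.9 to 52.0 ± 16.2 CPM (list median 0.18, adjusted p = 0.133 with an estimated correlation). PDGFB (0.29), ANGPT2 (0.87, and 0.22 without CC-223 mouse 201) and NRP2 (0.39) did not pass. Interferon response genes were the only list called lower. None of its 36 members passed, over all genes or adjusted over the list alone, and 34 had a fold change below 0 (median -0.20, camera adjusted p 1.67e-06, adjusted p = 0.486 with an estimated correlation). The values were -1.50 (SE 0.45) for IRF7, -0.45 (SE 0.18) for MX2, -0.35 (SE 0.14) for IFIT1 and -0.37 (SE 0.15) for IRF1.

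**Figure D2:**
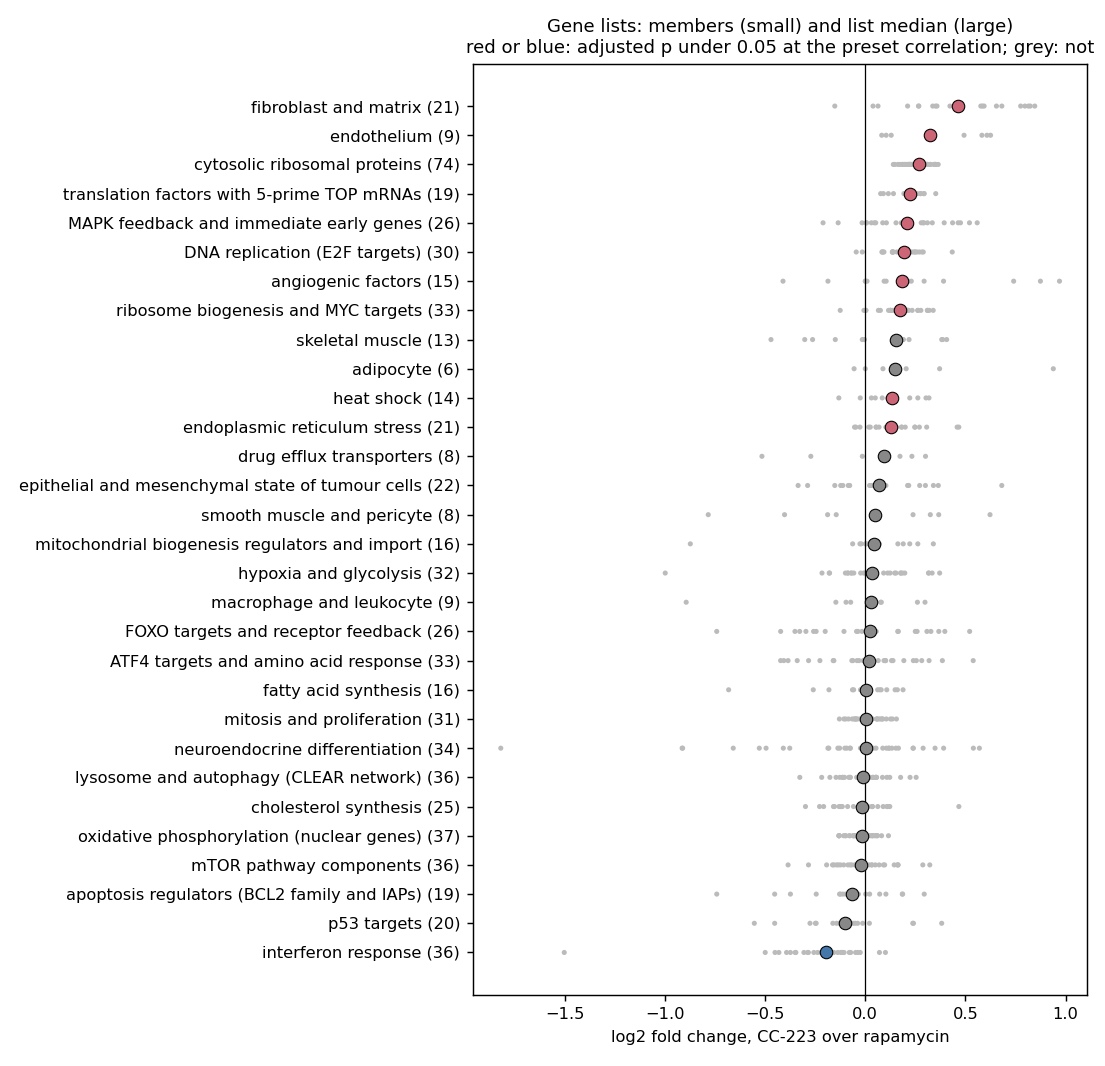
Log2 fold change of CC-223 over rapamycin for the members (small points) and the median (large points) of the 30 tested lists, with the number of measured members in parentheses. Red medians mark the 10 lists called higher and the blue one the interferon list called lower at the preset correlation; none of the 30 passed with an estimated one.

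Lists of lipid, mitochondrial and lysosomal genes and of the mTOR pathway itself did not pass. The 25 cholesterol synthesis genes had a median of -0.01 (camera adjusted p 0.410). Among them IDI1 (-0.30), HMGCS1 (-0.21) and SREBF2 (-0.16) did not pass. Of 16 fatty acid synthesis genes 1 fell, ACSS2, which activates acetate (-0.68, SE 0.17, adjusted p 0.0396; 1 when adjusted over the list alone). MID1IP1 (0.19), ELOVL5 (0.16) and ACSL3 (0.15) did not pass. No member passed over all genes among 36 mTOR pathway components (median -0.02), 26 FOXO targets (0.02), 33 ATF4 targets (0.02), 36 lysosome and autophagy genes (-0.01), 32 hypoxia and glycolysis genes (0.03), 37 nuclear oxidative phosphorylation genes (-0.02) and 16 mitochondrial biogenesis genes (0.04). Adjusted over the list alone, 4 FOXO targets passed (3 higher, 1 lower), 3 ATF4 targets (2 higher, 1 lower), 2 mitochondrial biogenesis genes (1 higher, 1 lower), 1 lysosome gene (higher), 1 hypoxia gene (lower) and 0 in the mTOR and oxidative phosphorylation lists. The drug targets themselves did not pass: MTOR had a log2 fold change of -0.13 (SE 0.09), RPTOR 0.16 (SE 0.10) and RICTOR 0.03 (SE 0.12). Nor did EIF4EBP1, the translation repressor that mTOR phosphorylates (0.32, SE 0.16), or the insulin receptor substrates IRS1 (0.02, SE 0.10) and IRS2 (0.31, SE 0.10, adjusted p 0.141).

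Among 34 measured neuroendocrine genes DDC alone passed, over all genes and adjusted over the list alone. Chromogranin A (CHGA) was 15475 ± 8249.7 CPM with rapamycin and 11659.6 ± 7656.5 with CC-223 (log2 fold change -0.41, SE 0.38), synaptophysin (SYP) 93.9 ± 27.01 and 97.5 ± 27.5, and the serotonin-making enzyme TPH1 160 ± 129 and 84.95 ± 50.96 CPM (-0.91, SE 0.45, adjusted p 0.395). Secretogranin 2 (SCG2, 0.57, SE 0.20), PTPRN (0.54, SE 0.25) and somatostatin (SST, -1.82, SE 0.83) did not pass, and SST was 0.37 without rapamycin mouse 266. No member of the 31 mitosis genes (median 0.00), 20 p53 targets (-0.10), 8 drug efflux transporters (0.09) or 22 genes of epithelial and mesenchymal state (0.07) passed, over all genes or adjusted over the list alone. The proliferation marker MKI67 was 288 ± 65.9 CPM with rapamycin and 280 ± 63.0 with CC-223 (-0.04, SE 0.12). Of 19 apoptosis regulators 1 fell, BIRC3, an inhibitor of apoptosis (-0.74, SE 0.18, adjusted p 0.0348; 1 when adjusted over the list alone), while BCL2L1 (0.29), MCL1 (0.19) and BBC3 (-0.45) did not pass. The calls of ACSS2 and BIRC3 ended in 15 and 12 of the 27 fits without 1 tumour. The median was above 0 and the mean below it for the fatty acid, FOXO, neuroendocrine and macrophage lists, with the test pointing up for the first 2 and down for the others. Drug efflux transporters had a median and mean above 0 and a test pointing down.

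Markers of host cells, whose mouse mRNAs can add reads at conserved genes, were compared as mean log2 CPM per tumour. The endothelial list of 9 markers was higher with CC-223 by 0.31 (2.26 ± 0.20 with rapamycin, 2.57 ± 0.24 with CC-223; permutation adjusted p 0.0103), above the rapamycin median in 13 of 14 tumours. With the median of the markers in place of the mean the adjusted p was 0.517 (range over 3 alternatives 0.0105 to 0.517). None of the 9 passed alone, and 1 did when adjusted over the list alone. Camera gave an adjusted p of 0.0282 (adjusted p = 0.133 with an estimated correlation). The VEGF receptor KDR had a log2 fold change of 0.63 (SE 0.18, adjusted p 0.0890), VWF 0.61 (SE 0.33), EGFL7 0.32 (SE 0.18) and CDH5 0.49 (SE 0.29). Without rapamycin mouse 214 KDR was 0.83 and passed (adjusted p 0.00237), and CDH5 was 0.84. KDR also passed with DESeq2 (0.0353), with limma-voom without (0.0403) and with quality weights (0.00402) and with surrogate variables (0.00193). It missed the threshold in the other alternatives, such as the mouse number block (0.0643), with a range over 14 alternatives of 0.00193 to 0.175. The 21 fibroblast and matrix genes had a median of 0.46 and no passing member, over all genes or adjusted over the list alone (camera adjusted p 2.91e-05, adjusted p = 0.299 with an estimated correlation). Per tumour the difference was 0.43 (permutation adjusted p 0.0791), and 0.49 without the 2 sparse libraries (0.0263). COL12A1 (0.81), COL6A2 (0.78), COL1A2 (0.85) and POSTN (0.59) did not pass. Smooth muscle and pericyte markers (0.03), macrophage and leukocyte markers (-0.04), skeletal muscle markers (0.08) and adipocyte markers (0.19) did not differ beyond the spread between tumours, with 0 members past the threshold over all genes. Adjusted over the list alone, 1 smooth muscle marker and 1 macrophage marker were lower and 1 adipocyte marker was higher. Of the lists too short to test, peripheral nerve had 3 measured members. The myelin gene PMP22 rose by 0.82 on the log2 scale, and MBP, also expressed outside nerve, was 0.00 (SE 0.08). None of 4 erythroid or 4 skin markers passed.

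The last question was how far treatment ordered the tumours against their other variation, and whether the CC-223 arm was more varied. Component 1 held 26.5% of the variance and set CC-223 mouse 236 apart, and component 2 held 13.6% and set rapamycin mouse 235 apart. Component 5, with 6.61%, was the only one of the first 5 to differ between arms (difference -12.9, two-sided permutation test, adjusted p 0.0301), and with all kept genes in place of 2000 none did. The mean distance to the centre of the arm was 42.1 ± 15.8 with rapamycin and 44.8 ± 21.3 with CC-223, a difference of 2.66 (permutation p 0.746). A wider spread with CC-223 was not detected.

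**Figure D3:**
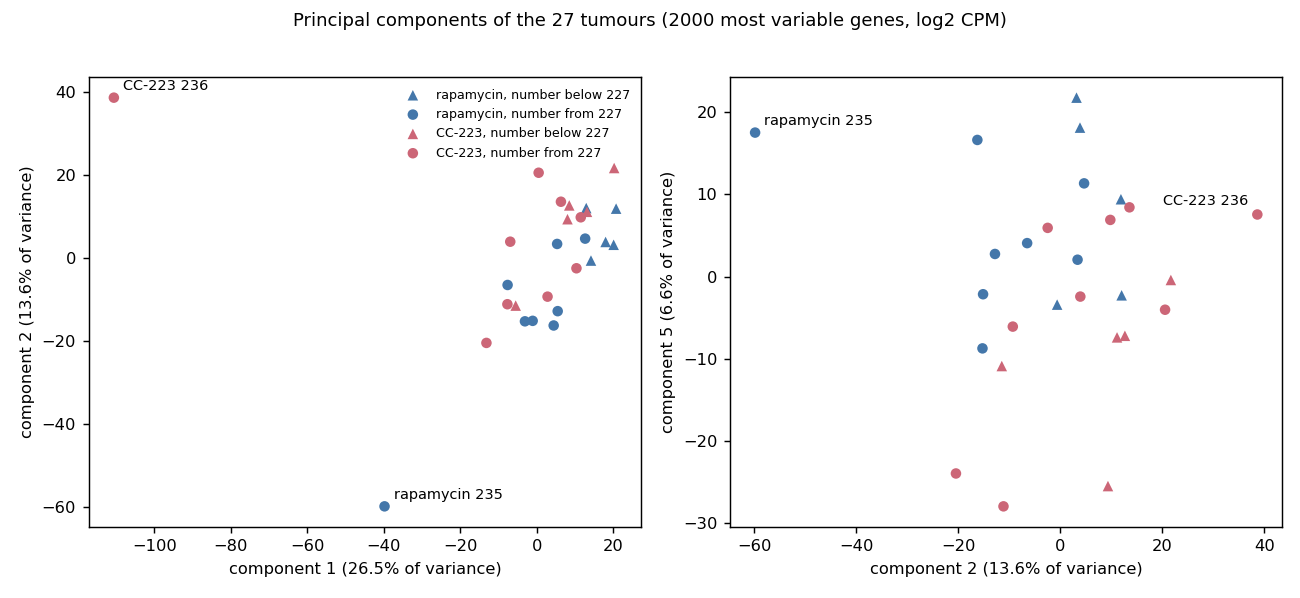
Scores of the 27 tumours on components 1 and 2 (left) and 2 and 5 (right), from log2 CPM of the 2000 most variable genes (blue: rapamycin; red: CC-223; triangles: mouse numbers below 227). CC-223 mouse 236 and rapamycin mouse 235 lie apart from the others, and the arms overlap on each component shown.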

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

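The variants without the 2 sparse libraries (rapamycin mouse 235, CC-223 mouse 236) and with mouse number below 227 as a block were chosen after seeing the data. No paired analysis was possible because the arms share no mouse number.

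Against 153 changed genes, RLE factors gave 142, upper quartile factors 149, limma-voom 131 and a mean of at least 5 CPM 161. Library totals alone gave 100 (47 higher, 53 lower), no filter on low counts 87 and an added 2-fold minimum 28. More genes were called by DESeq2 (378, 189 in each direction, all 153 among them), by voom with quality weights (445, 145 shared), with 6 surrogate variables (1372, all 153 among them), with the fibroblast level as a covariate (369, 130 shared) and at an adjusted p under 0.1 (332). Without the sparse libraries 196 genes were called (131 shared), with the mouse number block 227 (151 shared) and with both 269 (136 shared). Fewer genes at stricter thresholds follow from the setting; the cause of the other differences was not tested.

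Leaving out 1 tumour gave 66 to 239 genes. Besides rapamycin mouse 261 (66) and CC-223 mouse 245 (239), counts moved by over 1.5 times without rapamycin mice 203 (79), 206 (88), 207 (95) and 259 (72), and CC-223 mice 227 (83), 231 (83), 237 (84) and 268 (99). Of the named genes past the threshold, PHLDA1 missed it without rapamycin mouse 261 (adjusted p 0.0527), and EPHA4, DUSP4 and PPP1R15A missed it in 6, 13 and 15 of the 27 fits. Of the named genes that missed it, 23 passed with surrogate variables, 10 with quality weights, 7 with the fibroblast covariate, 5 with DESeq2 and at most 1 in other fits. Without 1 tumour KDR, EIF3E, IRF7 and MRTO4 passed once, PDIA6 9 times. CEL also missed it with quality weights (0.113) and the fibroblast covariate (0.0715), ACSS2 and TSR1 with voom (0.0644 and 0.0520), TSR1 and DUSP4 with the covariate (0.0522 and 0.0796), TSR1 and PPP1R15A with library totals (0.171 and 0.0567), and without a filter ACSS2 (0.0564), TSR1 (0.0554), DUSP4 (0.0595), BIRC3 (0.0507), HSP90B1 (0.0620) and PPP1R15A (0.0564). The fall of CPA1 was -6.05 on the log2 scale in mice numbered below 227 and -2.90 from 227.

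Of 11 lists called, 0 held with an estimated correlation, alone, with the block or without the sparse libraries, and 6 were called by fry, which also called p53 targets (adjusted p 0.0127), 7 in all. The fibroblast covariate kept 6 and added mitosis (0.0405) and mitochondrial biogenesis (0.0326), 8 in all. Leaving out 1 tumour gave 9 to 12. Heat shock was lost at 5 CPM (0.0698) and without rapamycin mouse 203 or 253 or CC-223 mouse 227, 231 or 263, endothelium without rapamycin mouse 244 or CC-223 mouse 245 or 258, and angiogenic factors without CC-223 mouse 245. Of 6 host lists, 1 passed. The count was 0 with the median of markers, 2 without the sparse libraries and 0 of 3 at 5 CPM, with endothelium not testable. Component calls went from 1 to 0 with all kept genes (adjusted p 0.227). The spread difference stayed between 0.51 and 2.60.
Reversals concerned values that missed the threshold, besides the fibroblast list under its own covariate. On the log2 scale MBP was -0.0064 with RLE factors, -0.042 with library totals, -0.0063 with DESeq2, -0.021 with quality weights, -0.0049 at 5 CPM, -0.028 with the fibroblast covariate, -0.032 without rapamycin mouse 266, -0.025 without the sparse libraries and -0.018 with the block as well. RICTOR was -0.015 with library totals, -0.0032 with quality weights, -0.055 with the covariate and -0.012 without mouse 266, and IRS1 was -0.032, -0.00061, -0.038 and -0.013 there and -0.0030 with the block and without the sparse libraries. SYP was -0.0050 with surrogate variables, MKI67 0.020 with the covariate and SST 0.37 without mouse 266. With RLE factors the medians of fatty acid synthesis, mitosis and neuroendocrine genes were -0.0066, -0.0065 and -0.0087, and mitosis was -0.0056 at 5 CPM. The covariate gave cholesterol 0.060, FOXO -0.025, oxidative phosphorylation 0.069, neuroendocrine -0.11, fibroblast -0.055, smooth muscle -0.22, macrophage -0.0065 and skeletal muscle -0.24. Without the sparse libraries hypoxia was -0.0086, macrophage -0.018 and the smooth muscle level -0.0048. The cause was not tested. The median of all genes was -0.04 with library totals, against 0.0013.
At this depth the test found 62% of simulated changes of 1.5-fold, over genes of all levels.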

Other observations

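The gene lists in this part were drawn up after the genes called were seen, so their counts are not independent evidence, and the tests of mouse number, of fragmented RNA and of tumour to tumour variation were chosen after the results were seen, as were further single genes. The tests of other splits, of pancreas RNA, of single tumours and of clock phase were set before their results were seen.

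Several further intestinal genes fell with CC-223, 13 of 35 measured members of an intestinal epithelium list in all (median log2 fold change -1.02). SI, the sucrase of the brush border, fell from 55.6 ± 21.9 to 27.4 ± 11.9 CPM. CA7, a carbonic anhydrase, fell from 12.9 ± 4.50 to 3.37 ± 4.19 CPM, and GUCA2B, the hormone uroguanylin, from 3.43 ± 1.96 to 1.26 ± 0.575 CPM. SPIB (-1.50) and BEST4 (-1.73), genes of specialised gut cells, fell too. Other intestinal genes stayed close: VIL1, the microvillus protein villin, had a log2 fold change of 0.15, CDH17 of -0.13 and TFF3 of 0.07. PDX1, the transcription factor of pancreas and duodenum, fell from 16.2 ± 4.04 to 10.1 ± 3.03 CPM (adjusted p 0.0294). In an acinar list of 12 measured genes the colipase CLPS (-4.58) fell beside CPA1 and CEL, and PTF1A, a regulator of acinar identity, was 0.54 (SE 0.23) and did not pass.

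LAMA3, a laminin chain, rose from 386 ± 152 to 797 ± 320 CPM (log2 fold change 1.05, adjusted p 0.00899). CYR61 (0.54) and CAV1 were the 2 of 21 YAP and TAZ targets that rose. TNFSF11, the cytokine RANKL, rose from 1.32 ± 0.585 to 4.32 ± 2.37 CPM, and PLAU, the protease urokinase, from 2.50 ± 1.52 to 6.10 ± 4.18 CPM.

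Chance splitting of the tumours was tested with 100 splits into 14 and 13, the real one included. As many genes as in the real split (153) were called in 2 of them, the real one included. At this share chance is an unlikely source of the gene count but is not excluded. The other one, at 1484 genes, points to a structure of the samples: it follows the mouse numbers, with 2 of the 10 low-numbered tumours on one side and 8 on the other. With mouse number as a block it called 0 genes and the real split 227. Each of the remaining splits called at most 1 gene. For the gene lists, 27 of the 100 splits called as many as the real 11, and the highest other called 17, so chance cannot be excluded for the number of lists called at the preset correlation. Compared as mean level per tumour, 7 of the 30 lists passed by permutation, and 7 with arms permuted within the mouse number parts. The adjusted p was 0.0099 for MAPK feedback, 0.0172 for angiogenic factors and for endothelium, 0.0337 for ribosome biogenesis, endoplasmic reticulum stress and p53 targets (lower), and 0.0401 for translation factors. This test, chosen after the results were seen, does not compare a list with other genes.

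The median log2 fold change of the 17 called acinar and intestinal genes (-1.66) was not carried by a single tumour: its value nearest to 0 without 1 tumour was -1.49. Of these genes 13 are intestinal, so that median cannot decide the question for the acinar part. For the called intestinal genes alone the median nearest to 0 was -1.34, without rapamycin mouse 259. For the called acinar genes it was -3.18, without rapamycin mouse 206. CEL went from -3.69 to -1.72 without mouse 206, still past the threshold. With mouse number as a block 15 of the 17 stayed past the threshold. This adds little, because the arms were nearly balanced over mouse numbers (5 tumours per arm below 227, 8 rapamycin and 9 CC-223 from 227). That balance, more than the block, argues against a difference between low and high numbers as the whole cause. Pancreas RNA in some tumours stays open for the acinar part: other abundant acinar mRNAs summed to 0.705 of the acinar enzymes called lower in the rapamycin arm (95% bootstrap interval 0.272 to 1.11) with 0.445 without mouse 206 and 0.931 without mouse 203, and the bound of 0.1 set in advance was not met. Those mRNAs were mostly PRSS1 (78.0 ± 200 CPM with rapamycin, 31.6 ± 14.6 with CC-223, adjusted p 0.319). They reached 744 CPM in mouse 206, against at most 63.6 in the other rapamycin tumours. With rapamycin PNLIP (0.0449 CPM), CTRB1 (0.555), CELA3A (0.851), CELA3B (1.45), CPB1 (1.57) and CTRB2 (1.76) were low. The ratio cannot decide the question, because these mRNAs also summed to 14.8 to 64.2 CPM in the CC-223 tumours. The acinar genes called lower summed to at most 29.6 CPM there. In rapamycin mouse 203 the sums were 54.4 CPM and 435 CPM, and in mouse 206 they were 744 CPM and 765 CPM. An effect of the switch in drug stays open and was not tested apart from these.

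The higher values of ribosomal protein mRNAs may be variation between tumours that these genes share: their mean level per tumour differed by 0.27 on the log2 scale (permutation p adjusted over the 30 lists 0.285). The level also differed with mouse number (9.12 with rapamycin and 9.41 with CC-223 below 227, 9.80 and 10.03 from 227), and with arms permuted within these parts the adjusted p was 0.128. Together with the translation factors the unadjusted permutation p was 0.103, and 0.0371 within the parts, which leaves the explanation open for the whole. For the translation factors alone (difference 0.22, above the rapamycin median in 12 of 14 tumours) the adjusted p of 0.0401, and 0.0189 within the parts, argues against it. Short mRNAs favoured in fragmented RNA stay open. The nuclear oxidative phosphorylation genes had a median of -0.017 (95% bootstrap interval over genes -0.050 to 0.0022), against 0.27 for ribosomal proteins. That interval leaves out the spread between tumours, so it cannot decide the question. Per tumour the mean level of this list was 7.12 ± 0.34 with rapamycin and 7.11 ± 0.31 with CC-223.

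Clock output genes were the third pattern: PER3, DBP (-0.69), TEF (-0.72) and NR1D2 (-0.44) fell, 4 of 10 measured. NR1D1 was -0.04 (SE 0.08). With mouse number as a block 4 of the 4 stayed past the threshold, which adds little because the arms were nearly balanced over mouse numbers. Different clock phases at collection cannot be told apart from an effect of the drug, because no collection time was used here and the genes of opposite phase differed by 0.026 (95% bootstrap interval -0.052 to 0.104), an interval that holds 0.

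One CC-223 tumour, mouse 201, had 463 CPM of CHGA, against 2689 to 29062 in the other 26. MALAT1, a nuclear non-coding RNA, was 2025 ± 967 CPM in the 10 mice numbered below 227 and 547 ± 210 CPM in the other 17. The effect of CC-223 was tested for a difference between those parts, and 0 genes passed (edgeR interaction term; 399 at an unadjusted p under 0.05).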
